A study of Homo sapiens with 16 samples.

How the data were processed

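RNA was measured by sequencing in 16 libraries of MDA-MB-231 cells, 4 each after DMSO, afatinib, paclitaxel and the combination of both drugs, per the labels. Cells were grown in DMEM with 10% FBS, and the treatment protocol in the labels also names doxorubicin, for which the series holds no sample. The labels give no dose or exposure time.

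The authors deposited a table of gene counts with integer values, made with STAR 2.7.5b on hg38 and featureCounts from Subread 2.0.1, per the submitters' processing notes. The authors also deposited a table of log2 values corrected for RNA concentration. A check of its values showed what was done: they equal log2 CPM from edgeR with TMM factors and a prior count of 2, minus a term linear in the labelled RNA concentration, to within 6.41e-14. The slopes of that term correlate by r = 1 with those of a regression on concentration without the treatment and by 0.954 with those within treatments, so the treatment was not in the model. All comparisons here start from the deposited counts, and the log2 table served only as an alternative. A further 2 numeric columns of the count table were not used.

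The count table held 37864 genes. Of their identifiers, 36220 were in the primary assembly annotation of GENCODE v29 and 1644 were not, 171 genes had no symbol (0.036 to 0.0462% of the counts of a library) and 369 symbols stood on more than 1 identifier. Genes were kept by filterByExpr of edgeR with a minimum count of 10 and a minimum total of 15, which left 17991. Library totals ran from 28.4M to 48.1M counts (median 42.7M), and the common biological coefficient of variation was 7.41%. Pairs of libraries of the same group differed by a χ² per gene of 6.62 to 336 over genes with at least 20 counts, so no library was a copy of another of its group.

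Replicates 1 and 2 carried higher labelled RNA concentrations than replicates 3 and 4 in every group, and these 2 concentration sets entered every fit as a term. Counts were scaled with TMM factors and tested with the robust quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with groups and set in the design and all 16 libraries in 1 fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each SE is the absolute log2 fold change divided by the square root of F. The comparisons were each treatment with DMSO, the combination with each single drug, and the interaction, which is the combination minus both single-drug changes. Principal components were computed from log2 CPM of the tested genes.

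Gene lists were fixed before the files were seen: 32 lists with 508 symbols, of which 499 matched and 4 of those under older names (among them RIGI as DDX58, CCN1 as CYR61, CCN2 as CTGF). ABCB1, CCL5, TNF, CMPK2, XBP1, HBB, TYROBP and DCN were not analysed here, since the table did not hold them under a matched symbol or they had too few counts. The lists are EGFR family, MAPK/ERK output, immediate-early, FOXO, mitosis, DNA replication, homologous recombination, p53, tubulin, BCL2 family, drug efflux, NF-kB, interferon, MHC class I, cholesterol, fatty acid, ATF4, endoplasmic reticulum chaperone, heat shock, NRF2, lysosome, hypoxia, YAP/TEAD, mesenchymal, epithelial, matrix protease, ribosomal, mitochondrially encoded, and markers of blood, fibroblast, endothelial and luminal breast cells. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. Members were also adjusted over the list alone. Of 74 list calls 14 also passed with the estimated correlation.

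The named-gene rule was set before the data were examined, as were the comparisons, the threshold, the lists and most of the alternatives below. Named are the called genes with the largest changes in each direction (8 against DMSO, 5 otherwise) that had an average log2 CPM of at least 3 and the same sign in both sets, up to 4 members of a list with the smallest p, and EGFR, ERBB2, ERBB4 and TUBB. Which of the up to 4 members of a list the text prints was chosen after their values were seen, with preference for calls that no single library changed. Some genes of the lists are not reported here by name. Positions come from GENCODE v29. TUBB, the HLA genes, TAP1, TAP2, TAPBP and PSMB8 stand on several identifiers from alternative assemblies, so their reads are divided.

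Replicate numbers were checked for pairing. Deviations from group means correlated between libraries of the same number by 0.37 to 0.70 (median 0.59, 24 pairs), each above 0.1, so the numbers pair the libraries. Libraries of the same set and different number correlated by 0.38 to 0.67 (median 0.5), so much of this pairing comes from the set. After removing the set means the same-number values were −0.12 to 0.13 (median 0). Those of the same set and different number were −0.30 to −0.04 (median −0.18). Libraries of the same number thus stayed somewhat more alike, and pairing by number beyond the set is not excluded. Fits with the replicate number as a block were run as an alternative. Tests of treatment by set called 0 genes with edgeR for each treatment (339, 552 and 1107 at an unadjusted p under 0.05 for afatinib, paclitaxel and the combination).

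The scripts were tested on simulated data with 50 genes changed per fold among 17991, drawn only from genes above a minimum mean count. The shares below therefore do not cover genes with low counts. Far fewer genes changed in the simulation than were called in the single-drug comparisons, and the shares depend on that number. For a single-drug comparison 54% of genes changed 1.25-fold, 90% of those changed 1.5-fold, 90% at 2-fold and 98% at 4-fold were called, and 6.21% of calls were unchanged genes. For the interaction these were 16, 60, 92 and 96%, with 5.04%. At this depth and replicate number, most interactions of 1.25-fold would be missed.

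Alternatives tried were no concentration term, the replicate block, the RNA concentration on a log2 or linear scale, each set alone, RLE size factors, library sizes without mitochondrial and the 10 most abundant genes, DESeq2 1.42.0, limma-voom, no filter, a null of 1.5-fold (glmTreat), the authors' log2 table with limma, only the groups compared, and leaving out each library. The linear scale and leaving out both libraries with the highest mitochondrial share were added after the data were seen. Other splits of the labels were refitted in full. Figures were drawn with python 3.11.15.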

Results

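The transcriptome of MDA-MB-231 cells, a human triple-negative breast cancer cell line, was measured by RNA sequencing after treatment with afatinib, paclitaxel, both drugs together (the combination) or the solvent DMSO. Afatinib irreversibly inhibits the kinases of the EGFR family, and paclitaxel stabilises microtubules and holds cells in mitosis. The series title names synthetic lethality of both drugs as its subject. Doses and exposure times were not given in the sources used here. Each group held 4 libraries, 16 in all. Library totals ranged from 28.4M to 48.1M counts with a median of 42.7M. Paclitaxel replicate 4 was the lowest. Of 37864 genes in the count table, 17991 had enough counts to be tested. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. Changes are given below as log2 fold changes ± SE from edgeR with 4 libraries per group, levels as CPM (counts scaled to library size) ± SD with n = 4, and positions on the GRCh38 assembly.

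Replicates 1 and 2 of every group carried higher labelled RNA concentrations (346 to 1291 ng/µl) than replicates 3 and 4 (118 to 330 ng/µl), and this split was the largest source of variation. The first principal component, with 43% of the variance, was below 0 in all 8 libraries of the first kind and above 0 in all 8 of the second. The second component (14.4%) ordered the treatments, from 24.6 to 26.9 in DMSO, 6.84 to 10.7 with afatinib, −11.8 to −4.84 with paclitaxel and −29.4 to −22.8 in the combination. The third component (12.2%) placed afatinib at 21.2 to 25.9 and paclitaxel at −27.8 to −22.6. Between both concentration sets 12508 genes differed, of which 6512 were higher in replicates 3 and 4. Long genes were higher there and short genes lower, with medians of −0.29 among the shortest of 4 equal length classes and 0.16 among the longest (log2, replicates 3 and 4 minus 1 and 2). Every comparison below therefore includes the concentration set as a term, and values within each set are printed beside the pooled ones for the main genes and for list medians. This term does not remove the difference in concentration between treatments. In replicates 1 and 2 the mean was 1171 ng/µl in DMSO and 388 ng/µl with paclitaxel. The changes with each treatment can therefore hold a part that goes with concentration. The SDs of CPM levels span both sets, so they hold the difference between the sets too.

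**Figure D1:**
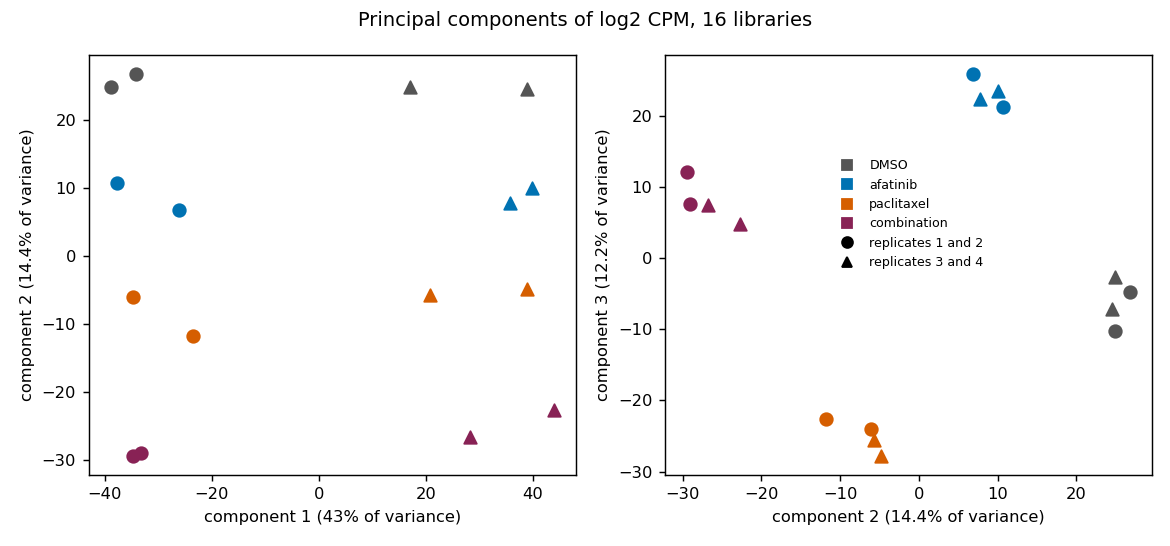
Principal components of log2 CPM over the tested genes, 1 point per library, coloured by treatment; circles are replicates 1 and 2, triangles replicates 3 and 4. Component 1 (43% of variance) parts the concentration sets, and components 2 (14.4%) and 3 (12.2%) part the treatments.

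The transcripts of the drugs' own targets were measured first. EGFR (ENSG00000146648, chromosome 7, 55019021 to 55211628), the receptor tyrosine kinase that afatinib inhibits, stood at 725 ± 279 CPM in DMSO, 713 ± 244 with afatinib, 597 ± 189 with paclitaxel and 676 ± 294 in the combination. EGFR fell with paclitaxel (−0.26 ± 0.09, adjusted p = 0.0376, −0.18 and −0.32 within the sets), a call lost without DMSO replicate 1 (adjusted p = 0.179), DMSO replicate 4 (0.139) or paclitaxel replicate 2 (0.0648), 3 (0.132) or 4 (0.0701). Its difference was −0.02 ± 0.09 with afatinib and −0.13 ± 0.09 in the combination. Among the leave-outs the latter passed only without combination replicate 4 (−0.22, adjusted p = 0.0317). ERBB2, the second receptor blocked by afatinib, stood at 74.3 ± 22 CPM in DMSO and differed by −0.08 ± 0.07, −0.06 ± 0.07 and −0.00 ± 0.07, none past the threshold. ERBB4 had 1 to 6 counts per library and was not tested. TUBB, a β-tubulin gene whose product binds paclitaxel, fell from 33.3 ± 2.72 CPM in DMSO to 20.9 ± 1.46 with paclitaxel (−0.67 ± 0.07) and 17.2 ± 0.82 in the combination (−0.95 ± 0.07). It fell by 0.24 ± 0.07 with afatinib, a call lost without afatinib replicate 3 (adjusted p = 0.0609), afatinib replicate 4 (0.0838) or DMSO replicate 2 (0.0820). TUBB reads were divided over 5 gene identifiers, all outside the primary assembly, so its level is uncertain.

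Afatinib versus DMSO asked which transcripts change when the EGFR family is inhibited alone. Several of the genes with the largest falls encode secreted inflammatory factors. CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716), the chemokine interleukin 8, fell from 108 ± 32.9 to 32.6 ± 10.1 CPM (−1.69 ± 0.28, adjusted p = 0.00165, −1.62 and −1.86 within the sets). The proteoglycan ESM1 (−1.79 ± 0.17), the chemokine CXCL1 (−1.38 ± 0.14), the cytokine IL1A (−1.29 ± 0.12), the matrix protein THBS1 (−1.33 ± 0.19) and CTGF (−1.25 ± 0.25), a matricellular growth factor, fell as well. So did TRIM25 (−1.21 ± 0.08), a ubiquitin ligase of antiviral signalling, and the protease ADAMTS6 (−1.17 ± 0.10). CLU, which encodes the secreted chaperone clusterin, rose from 7.24 ± 2.11 to 15.8 ± 4.96 CPM (1.11 ± 0.10), along with MEGF6 (1.2 ± 0.10), the zinc finger gene ZNF114 (1.07 ± 0.07) and the mitochondrially encoded MT-ND6 (1.52 ± 0.33), MT-TN (1.49 ± 0.19) and MT-ND5 (1.09 ± 0.26).

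Among the gene lists, NF-kB targets and inflammatory cytokines showed the largest shift with afatinib: 12 of 20 tested members fell and 1 rose (median −0.47, −0.48 and −0.46 within the sets; camera adjusted p = 2.55e-11), led by IL1B (−1.55 ± 0.16), IL11 (−1.14 ± 0.10) and CXCL3 (−1.04 ± 0.12). Targets of YAP/TEAD, the transcription factors of the Hippo pathway, fell in 11 of 15 cases, including the clotting initiator F3 (−0.85 ± 0.09) and TGFB2 (−0.53 ± 0.07). Of 12 mesenchymal genes 5 fell, among them the intermediate filament gene VIM (−0.35 ± 0.06). Of 11 matrix proteases and members of the plasminogen system 4 fell, including PLAU (−0.79 ± 0.10) and MMP14 (−0.68 ± 0.10), with list medians of −0.51 and −0.23 within the sets. Genes transcribed downstream of MAPK/ERK fell in 8 of 18 cases and rose in 1, with ETV4 at −0.41 ± 0.06 and PHLDA1 at −0.30 ± 0.05. In the list of EGFR family members, ligands and regulators 5 of 12 fell and 2 rose. The ligands HBEGF (−0.79 ± 0.07) and TGFA (−0.35 ± 0.05) were lower, and BTC was higher (0.97 ± 0.14). That list lost its call (adjusted p = 0.0399) without afatinib replicate 2 (0.0644), afatinib replicate 4 (0.0761), DMSO replicate 1 (0.0575) or DMSO replicate 4 (0.144). Adjusted over the list alone, 13 NF-kB genes fell and 2 rose, 12 YAP/TEAD, 6 mesenchymal and 4 protease genes fell, 8 MAPK/ERK genes fell and 3 rose, and 5 EGFR family genes fell and 2 rose. None of these calls held with an estimated correlation: adjusted p = 0.0586 with an estimated correlation for NF-kB, 0.249 for YAP/TEAD, 0.129 for mesenchymal genes, 0.417 for proteases, 0.345 for MAPK/ERK and 0.446 for the EGFR family.

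Afatinib also lowered lists of protein synthesis and folding. Endoplasmic reticulum chaperones fell in 7 of 15 cases (DNAJB9 −0.58 ± 0.09, HERPUD1 −0.39 ± 0.07) and ribosomal proteins in 11 of 20 (median −0.17, −0.17 in each set). Targets of ATF4, the factor of the amino acid response, fell in 9 of 21 and rose in 1, with the amino acid transporter SLC7A5 at −0.50 ± 0.07 and the stress factor DDIT3 at 0.52 ± 0.11. DNA replication genes fell in 9 of 28 and rose in 1 (RRM2 −0.36 ± 0.05), and tubulin isotypes fell in 4 of 10 (TUBB6 −0.33 ± 0.06). Higher lists were NRF2 targets of the antioxidant response (7 of 14, median 0.19, 0.19 and 0.20 within the sets, with FTL at 0.44 ± 0.07 and HMOX1 at 0.54 ± 0.10) and lysosome and autophagy genes (5 of 19 rose and 1 fell, with SQSTM1 at 0.63 ± 0.07). Interferon-stimulated genes rose in 7 of 30 cases (PARP9 0.43 ± 0.08), a list call lost without afatinib replicate 1 (adjusted p = 0.0888). FOXO and PI3K-inhibition targets rose in 6 of 16 (PIK3IP1 0.57 ± 0.13), lost without afatinib replicate 2 (0.0969), afatinib replicate 3 (0.0993) or DMSO replicate 4 (0.0764). With p-values adjusted over the list alone, 10 chaperone, 13 ribosomal and 6 tubulin genes fell, 10 ATF4 targets fell and 2 rose, 10 replication genes fell and 1 rose, 8 NRF2 targets rose, 7 lysosome genes rose and 1 fell, 9 interferon genes rose and 1 fell, and 6 FOXO targets rose. Each of these calls was lost, with adjusted p = 0.0999 with an estimated correlation for NRF2 targets, 0.249 for ATF4, 0.345 for chaperones and for interferon, 0.417 for ribosomal proteins, tubulins and FOXO, 0.434 for lysosome and 0.446 for replication.

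The mitotic kinase gene AURKB (0.27 ± 0.06) alone rose among 30 mitosis genes with afatinib, also when adjusted over the list alone. The list passed at a median of 0.07 (0.12 and 0.04 within the sets, adjusted p = 0.0413; adjusted p = 0.540 with an estimated correlation). That call was lost without afatinib replicate 2 (0.109) or 4 (0.111) or DMSO replicate 1 (0.0504) or 2 (0.101). Mitochondrially encoded transcripts rose in 6 of 13 cases with afatinib (median 0.34, 0.17 and 0.54 within the sets), the same 6 when adjusted over the list alone, with MT-ND4 at 1.02 ± 0.21 (adjusted p = 0.493 with an estimated correlation for the list). Their share of all counts was 3.36 ± 1.23% in DMSO and 4.98 ± 2.5% with afatinib (2.32 and 2.82% in replicates 1 and 2, 4.40 and 7.14% in replicates 3 and 4). A two-sided exact permutation within the sets gave p = 0.0556, the smallest its 36 arrangements allow. MTND6P4 (1.45 ± 0.31) and MTND5P11 (1.09 ± 0.25) are nuclear copies that share reads with MT-ND6 and MT-ND5 and are uncertain. Of the 31 lists with a test 17 passed, none with an estimated correlation. In all, 3432 genes, 19.1% of those tested, passed at an adjusted p under 0.05 with edgeR, 1620 higher and 1812 lower. Of these 247 changed more than 2-fold (167 higher, 80 lower). The count was 1243 within replicates 1 and 2, 516 within replicates 3 and 4, and 380 (219 higher, 161 lower) without the concentration term. With 1.5-fold as the null it was 57.

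**Figure D2:**
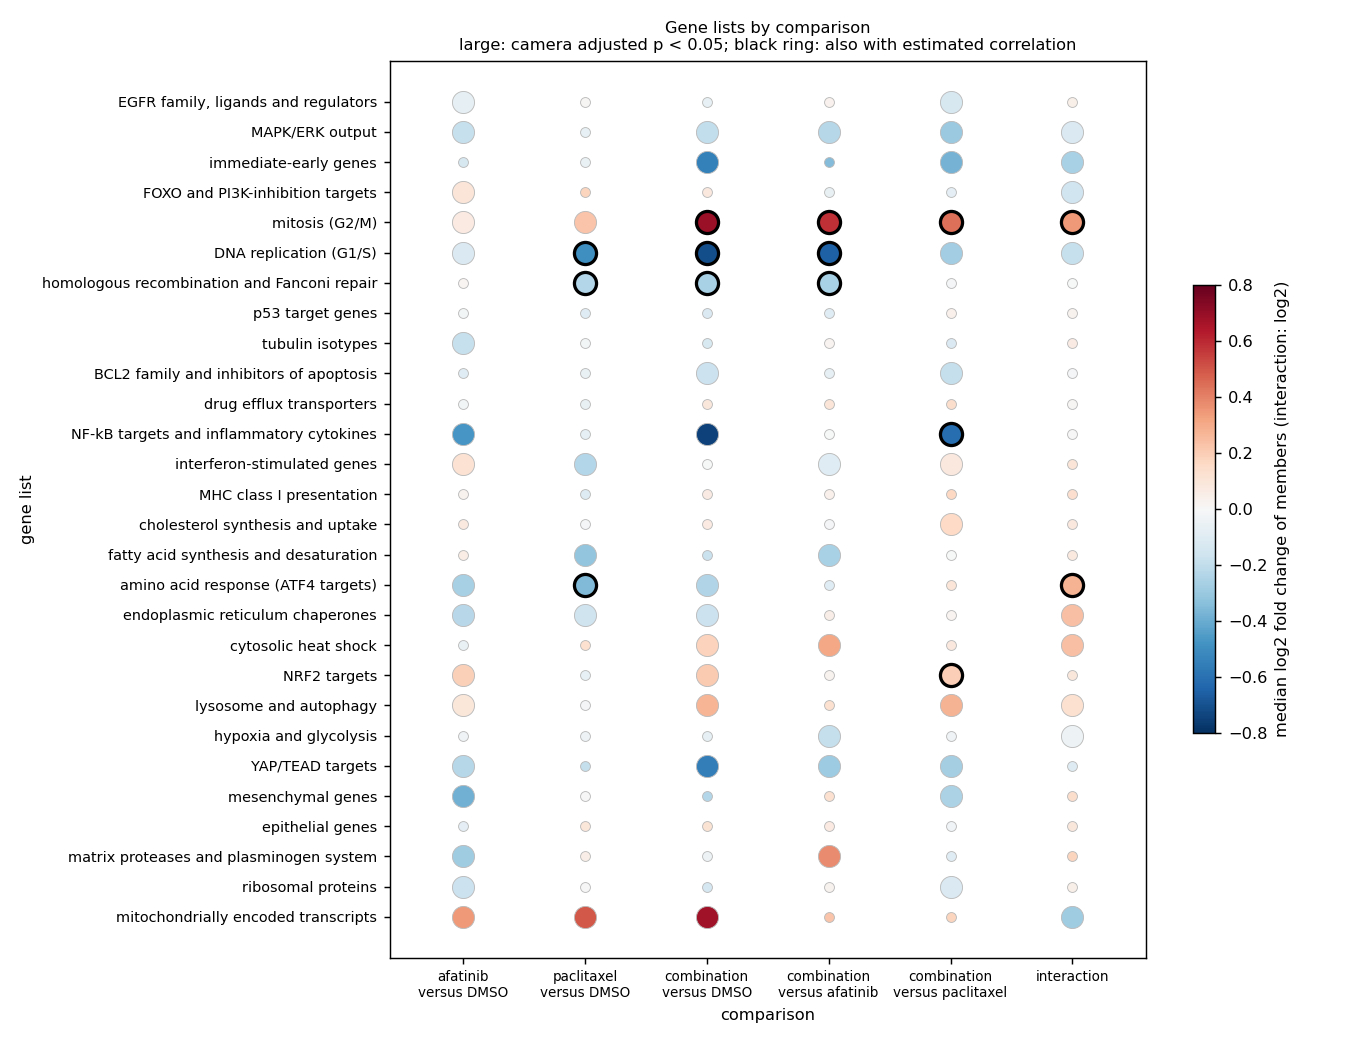
Median log2 fold change (colour) of the 28 gene lists that do not mark other cell types, in the 6 comparisons. Large points have a camera adjusted p under 0.05 with a preset correlation of 0.01, and a black ring marks those that also pass with an estimated correlation, such as mitosis and DNA replication in the combination versus DMSO.

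Paclitaxel versus DMSO asked for the response to microtubule stabilisation alone. HIST1H2BK (ENSG00000197903, chromosome 6, 27146418 to 27146798), a histone H2B gene, rose from 6.61 ± 1.28 to 20.7 ± 2.47 CPM (1.65 ± 0.09, adjusted p = 6.04e-12, 1.57 and 1.73 within the sets), and the linker histone gene HIST1H1C rose by 0.92 ± 0.13. Other rises were in ARRDC3 (1.42 ± 0.15), an arrestin-domain regulator of receptor trafficking, the lipoprotein lipase inhibitor ANGPTL4 (1.09 ± 0.17), the channel subunit ABCC9 (1.04 ± 0.10), TMEM71 (0.89 ± 0.12) and the small GTPases RRAD (0.89 ± 0.10) and GEM (0.88 ± 0.07). PSAT1 (ENSG00000135069, chromosome 9, 78297143 to 78330093), an enzyme of serine synthesis, fell from 236 ± 27.5 to 103 ± 10.7 CPM (−1.19 ± 0.07). The cell cycle transcription factor E2F1 (ENSG00000101412, chromosome 20, 33675683 to 33686404) fell from 106 ± 10.1 to 55.5 ± 4.09 CPM (−0.93 ± 0.06, −1.07 and −0.79 within the sets). CSF2 (−1.1 ± 0.17), DPYSL2 (−1 ± 0.08), the insulin receptor gene INSR (−1 ± 0.10), NCSTN (−0.95 ± 0.10), APOL6 (−0.94 ± 0.08) and the amino acid transporter SLC1A4 (−0.93 ± 0.12) fell too.

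The cell cycle lists moved with paclitaxel in opposite directions. Of 28 DNA replication genes 26 fell (median −0.49, −0.55 and −0.41 within the sets; camera adjusted p = 8.79e-42, adjusted p = 0.0134 with an estimated correlation), including the helicase subunit MCM6 (−0.76 ± 0.07), its partner in the active helicase CDC45 (−0.70 ± 0.06) and the ribonucleotide reductase subunit RRM2 (−0.59 ± 0.05). Homologous recombination and Fanconi repair genes fell in 9 of 15 cases (0.00381 with an estimated correlation), with EXO1 at −0.63 ± 0.06 and BRCA1 at −0.48 ± 0.05. Mitosis genes rose in 16 of 30 and fell in 7: the kinesin KIF20A (0.85 ± 0.07), cyclin B1 gene CCNB1 (0.69 ± 0.06) and CDC20 (0.62 ± 0.06) rose while the spindle protein NUSAP1 fell (−0.61 ± 0.06), and the list call was lost with adjusted p = 0.396 with an estimated correlation. ATF4 targets fell in 13 of 21 and rose in 1 (0.0117 with an estimated correlation), with CHAC1 at −1.63 ± 0.12 and MTHFD2 at −0.68 ± 0.07. Interferon-stimulated genes fell in 14 of 30 (DDX58 −0.56 ± 0.06), and genes of fatty acid synthesis in 8 of 10 (ACLY −0.39 ± 0.06), both with adjusted p = 0.0661 with an estimated correlation. Endoplasmic reticulum chaperones fell in 5 of 15 (0.665 with an estimated correlation), a call lost without DMSO replicate 4 (0.114) or paclitaxel replicate 3 (0.0581). When adjusted over the list alone, 26 replication, 11 repair, 16 interferon, 9 fatty acid and 6 chaperone genes fell, 18 mitosis genes rose and 7 fell, and 14 ATF4 targets fell and 2 rose.

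Several lists held strong single responses to paclitaxel without a list call. Of all tested genes 20.5% were called with paclitaxel, and the counts for p53, BCL2, hypoxia and efflux genes below are near that share. Among p53 targets 4 of 20 fell and 1 rose, with the cyclin kinase inhibitor CDKN1A at −0.76 ± 0.08 (MDA-MB-231 carries mutant p53). In the BCL2 family and inhibitors of apoptosis 4 of 16 fell, including MCL1 (−0.46 ± 0.06) and BCL2L1 (−0.33 ± 0.06). Genes of hypoxia and glycolysis rose in 2 and fell in 3 of 17 (VEGFA −0.50 ± 0.07), and the drug efflux transporter ABCG2 rose (0.60 ± 0.10), alone among 7. FOXO targets rose in 5 and fell in 2 of 16 (TXNIP 0.52 ± 0.07, adjusted p = 0.0797), a list that passed with the replicate number as a block (0.0360), without DMSO replicate 3 (0.0402) or without paclitaxel replicate 1 (0.0418). YAP/TEAD targets fell in 7 and rose in 2 of 15 (LATS2 0.32 ± 0.06, adjusted p = 0.0605) and passed with the block (0.0149) and without DMSO replicate 2 (0.0244), DMSO replicate 3 (0.00566) or paclitaxel replicate 1 (0.0350). Adjusted over the list alone, 5 p53 targets fell and 1 rose, 5 BCL2 family genes fell and 1 rose, 2 hypoxia genes rose and 3 fell, 1 efflux gene rose, 5 FOXO targets rose and 2 fell, and 9 YAP/TEAD targets fell and 3 rose.

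Mitochondrially encoded transcripts rose in 5 of 13 cases with paclitaxel (median 0.50, 0.43 and 0.56 within the sets), also 5 when adjusted over the list alone (adjusted p = 0.664 with an estimated correlation), and their share of counts was 4.94 ± 2.25% (3.32 and 6.56% within the sets against 2.32 and 4.40% in DMSO, exact permutation p = 0.0556). Of the 31 lists 8 passed, 3 also with an estimated correlation. Paclitaxel changed 3694 genes, 1557 higher and 2137 lower. Of these 270 changed more than 2-fold, 246 higher and 24 lower. Most of the 246 had an average log2 CPM under 3. At or above that level HIST1H1C, among the 8 largest rises, already changed less than 2-fold. Called genes at that level with the same sign in both sets were 872 higher and 1794 lower. The count of all changed genes was 1798 within replicates 1 and 2, 772 within replicates 3 and 4, 625 without the concentration term and 66 (52 higher, 14 lower) with 1.5-fold as the null. On the authors' concentration-corrected table it was 1148 (240 higher, 908 lower).

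The combination versus DMSO showed the largest response. CTGF (ENSG00000118523, chromosome 6, 131948176 to 131951373) fell from 543 ± 172 to 121 ± 62.7 CPM (−2.27 ± 0.26, −2.65 and −1.88 within the sets), and CXCL8 to 24.6 ± 10.3 CPM (−2.16 ± 0.29). CCNE2 (ENSG00000175305, chromosome 8, 94879770 to 94896678), the cyclin E2 gene of S phase entry, fell from 29.4 ± 0.28 to 7.52 ± 1.6 CPM (−1.98 ± 0.09, adjusted p = 7.42e-14, −2.23 and −1.74 within the sets). The cytokine genes CSF2 (−1.95 ± 0.18) and IL1A (−1.68 ± 0.12), the endothelin gene EDN1 (−1.92 ± 0.18), CXCL1 (−1.79 ± 0.14) and THBS1 (−1.61 ± 0.19) fell as well. GAS2L3, which links actin and microtubules, rose from 33.7 ± 4.29 to 105 ± 7.17 CPM (1.65 ± 0.08), with ARRDC3 (1.67 ± 0.15), GEM (1.58 ± 0.07), CLU (1.45 ± 0.10) and the mitochondrial tRNA genes MT-TN (2.00 ± 0.19) and MT-TC (1.59 ± 0.18).

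All 28 DNA replication genes fell in the combination (median −0.71, −0.79 and −0.65 within the sets; adjusted p = 0.0129 with an estimated correlation). E2F1 fell by 1.51 ± 0.06 to 36.9 ± 2.19 CPM, PCNA by 1.03 ± 0.06 and MCM6 by 1.21 ± 0.07. Mitosis genes rose in 25 of 30 cases and fell in 4 (median 0.69, 0.65 and 0.64 within the sets; 0.0133 with an estimated correlation): KIF20A (ENSG00000112984, chromosome 5, 138178719 to 138187715) rose from 132 ± 7.59 to 339 ± 17.7 CPM (1.36 ± 0.07), CCNB1 by 1.1 ± 0.06 and the mitotic kinase gene PLK1 by 0.85 ± 0.05. Repair genes fell in 10 of 15 (0.0163 with an estimated correlation), with the exonuclease gene EXO1 at −0.74 ± 0.06. With p-values adjusted over the list alone, 28 replication and 13 repair genes fell, and 25 mitosis genes rose and 4 fell.

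Signalling and stress lists also moved in the combination, where 38.0% of all tested genes were called. NF-kB targets fell in 13 of 20 cases and rose in 2 (IL1B −2.03 ± 0.16), YAP/TEAD targets fell in 10 of 15 and rose in 1 (ANKRD1 −1.26 ± 0.09), and MAPK/ERK output fell in 9 of 18 and rose in 1, led by the ERK phosphatase gene DUSP6 (−1.20 ± 0.08). Immediate-early genes fell in 8 of 15 (KLF6 −0.80 ± 0.09, JUNB −0.83 ± 0.10), and ATF4 targets fell in 12 of 21 and rose in 1. The BCL2 list fell in 8 of 16 and rose in 2 (MCL1 −0.74 ± 0.07, BIRC3 0.57 ± 0.07), a list call lost without combination replicate 4 (adjusted p = 0.0586) or DMSO replicate 3 (0.0669). Heat shock genes rose in 6 of 11 (HSPH1 0.54 ± 0.06, BAG3 0.49 ± 0.06), NRF2 targets in 6 of 14 (OSGIN1 0.97 ± 0.08), and lysosome genes rose in 11 of 19 and fell in 1. Endoplasmic reticulum chaperones fell in 6 of 15, a list call (0.0482) lost without combination replicate 1 (0.0711), 2 (0.0674) or 3 (0.0830) or DMSO replicate 2 (0.0788) or 4 (0.165). Among p53 targets, which had no list call, 8 of 20 fell and 3 rose (CDKN1A −0.98 ± 0.08). When adjusted over the list alone, 13 NF-kB genes fell and 2 rose, 11 YAP/TEAD fell and 1 rose, 9 MAPK/ERK fell and 2 rose, 8 immediate-early and 6 chaperone genes fell, 13 ATF4 targets fell and 1 rose, 8 BCL2 family genes fell and 2 rose, 6 heat shock and 7 NRF2 genes rose, 14 lysosome genes rose and 1 fell, and 8 p53 targets fell and 3 rose. These list calls were lost, with adjusted p = 0.0662 with an estimated correlation for NF-kB and MAPK/ERK, 0.0939 for YAP/TEAD, ATF4, BCL2 and NRF2, 0.352 for immediate-early, heat shock and lysosome genes and 0.607 for chaperones.

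Mitochondrially encoded transcripts rose in 8 of 13 cases in the combination, also 8 when adjusted over the list alone (median 0.68, 0.35 and 1.00 within the sets; adjusted p = 0.512 with an estimated correlation), with MT-ND4 at 1.39 ± 0.21 and MT-ND6 at 1.54 ± 0.33 beside its copy MTND6P4 (1.5 ± 0.31, uncertain). Their share of counts was 5.98 ± 3.3% (3.21 and 8.74% within the sets, exact permutation p = 0.0556), and the geometric mean of the labelled RNA concentration was 0.491 of that of DMSO (exact permutation p = 0.0556), against 0.711 with afatinib and 0.514 with paclitaxel (p = 0.111 each). The arithmetic means were 741 ng/µl in DMSO, 593 with afatinib, 320 with paclitaxel and 383 in the combination. Of the 31 lists 14 passed, 3 also with an estimated correlation. The combination changed 6830 genes, 3327 higher and 3503 lower, 620 of them more than 2-fold (424 higher, 196 lower). Within replicates 1 and 2 the count was 4671, within replicates 3 and 4 it was 3169, without the concentration term 2310 and with 1.5-fold as the null 471.

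**Figure D3:**
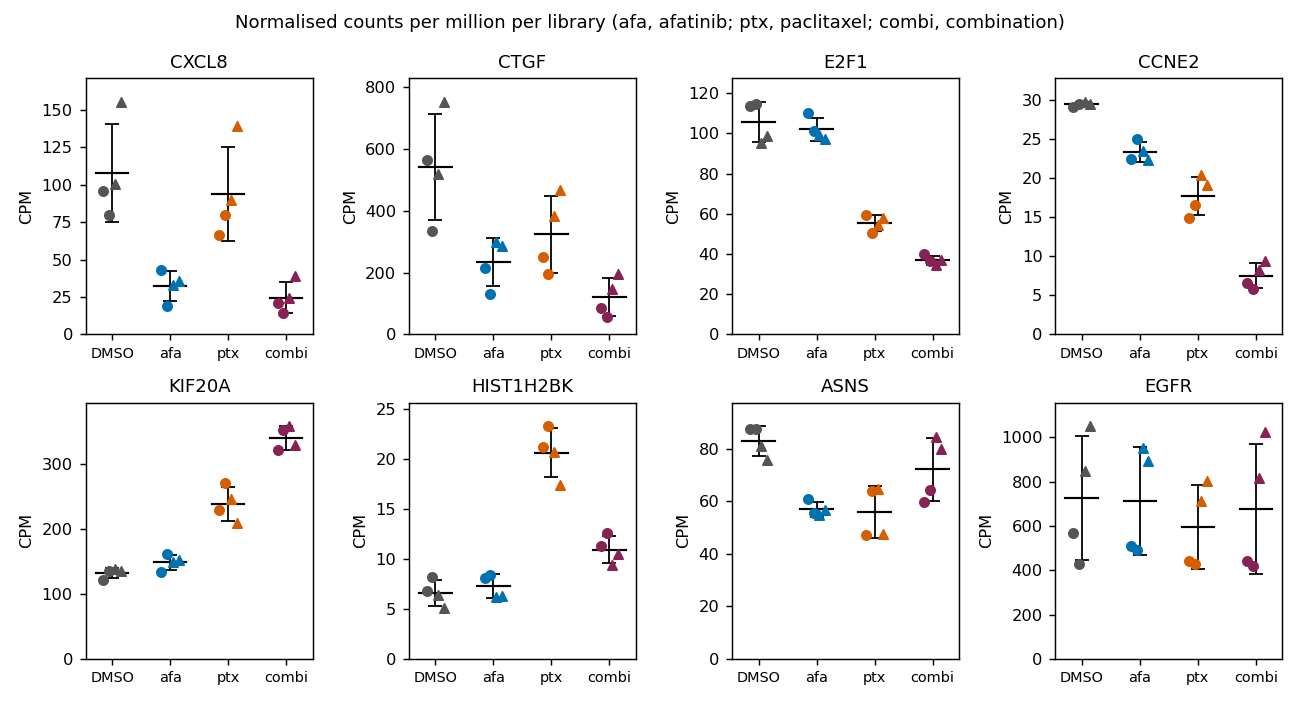
Levels in CPM of CXCL8, CTGF, E2F1, CCNE2, KIF20A, HIST1H2BK, ASNS and EGFR, 1 point per library by treatment, with bars for the mean ± SD (n = 4). CCNE2 stands at 7.52 CPM in the combination against 29.4 in DMSO, and EGFR overlaps between all groups. Each SD spans both concentration sets and holds the difference between them.

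The combination versus afatinib gives the effect of paclitaxel on cells that also received afatinib. Among the genes with the largest rises, KIF20A went from 148 ± 11.5 to 339 ± 17.7 CPM (1.2 ± 0.07, 1.2 and 1.19 within the sets). The mitotic kinase gene AURKA rose by 1.14 ± 0.07, the kinesin gene KIF18A by 1.11 ± 0.06 and GAS2L3 by 1.2 ± 0.08. TMEM71 rose by 1.09 ± 0.12. CCNE2 (−1.65 ± 0.10), E2F1 (−1.47 ± 0.06, −1.47 and −1.46 within the sets), CSF2 (−1.32 ± 0.18), the uracil-DNA glycosylase gene UNG (−1.25 ± 0.08) and FAM111B (−1.18 ± 0.07) fell. Mitosis genes rose in 25 of 30 cases and fell in 5 (median 0.59, 0.57 and 0.58 within the sets), all 28 replication genes fell (median −0.66, −0.71 and −0.58 within the sets), with E2F2 at −1.53 ± 0.10, and 12 of 15 repair genes fell, with EXO1 at −0.74 ± 0.06. Each of these calls held, with adjusted p = 0.00429 with an estimated correlation. Adjusted over the list alone, 25 mitosis genes rose and 5 fell, 28 replication genes fell and 12 repair genes fell.

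Paclitaxel on top of afatinib also raised 8 of 11 cytosolic heat shock genes, among them BAG3 (0.61 ± 0.06) and HSPH1 (0.59 ± 0.06). MAPK/ERK output fell in 9 of 18 cases and rose in 3 (SPRY1 −1.01 ± 0.11), YAP/TEAD targets fell in 10 of 15 and rose in 2, interferon-stimulated genes fell in 8 of 30 (HERC5 −0.62 ± 0.08) and fatty acid genes in 6 of 10 (ELOVL6 −0.43 ± 0.06). Hypoxia genes fell in 7 of 17 (VEGFA −0.48 ± 0.07), a list call (adjusted p = 0.0272) lost without afatinib replicate 2 (0.0549), afatinib replicate 3 (0.0553) or combination replicate 1 (0.0823). Matrix proteases rose in 5 of 11 (PLAUR 0.48 ± 0.08), lost without combination replicate 4 (0.205). Immediate-early genes fell in 5 and rose in 1 of 15 (adjusted p = 0.0519) and passed with the replicate block (0.0211) and without afatinib replicate 2 (0.0278), afatinib replicate 4 (0.0222), combination replicate 1 (0.0416) or combination replicate 3 (0.0284). With p-values adjusted over the list alone, 8 heat shock genes rose, 9 MAPK/ERK genes fell and 3 rose, 11 YAP/TEAD fell and 3 rose, 8 interferon, 7 fatty acid and 7 hypoxia genes fell, 7 protease genes rose, and 6 immediate-early genes fell and 1 rose. The list calls were lost, with adjusted p = 0.240 with an estimated correlation for heat shock, 0.273 for MAPK/ERK, 0.320 for interferon and fatty acid genes, 0.513 for hypoxia, 0.523 for YAP/TEAD and 0.624 for proteases. Of the 31 lists with a test 10 passed and 3 also with an estimated correlation. In this comparison 4935 genes changed (27.4% of those tested), 2359 higher and 2576 lower. The count was 2533 within replicates 1 and 2, 2003 within replicates 3 and 4, 1143 without the concentration term and 107 with 1.5-fold as the null.

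The combination versus paclitaxel gives the effect of afatinib on cells that also received paclitaxel. CXCL8 fell from 93.7 ± 31.6 to 24.6 ± 10.3 CPM (−1.94 ± 0.29, −2.06 and −1.86 within the sets), with CTGF (−1.47 ± 0.25), CXCL1 (−1.36 ± 0.14), IL1A (−1.31 ± 0.12) and THBS1 (−1.29 ± 0.19). CLU rose from 9.61 ± 2.24 to 20.2 ± 7.51 CPM (1.04 ± 0.10), and the tRNA genes MT-TN (1.77 ± 0.19) and MT-TC (1.26 ± 0.17) rose too. Mitosis genes rose in 28 of 30 cases (median 0.44, 0.35 and 0.50 within the sets; adjusted p = 0.0220 with an estimated correlation). KIF2C (ENSG00000142945, chromosome 1, 44739818 to 44767767), a microtubule depolymerase, stood at 173 ± 8.29 CPM with paclitaxel and 254 ± 24.6 in the combination (0.55 ± 0.05). NF-kB targets fell in 13 of 20 and rose in 2 (0.0251 with an estimated correlation), with IL1B at −1.87 ± 0.17 and TNFAIP3 at −0.68 ± 0.07. NRF2 targets rose in 6 of 14 (0.0400 with an estimated correlation), with HMOX1 at 0.73 ± 0.10. When adjusted over the list alone, 30 mitosis and 9 NRF2 genes rose, and 14 NF-kB genes fell and 2 rose. MT-ND6 rose by 1.02 ± 0.33, lost without combination replicate 2 (adjusted p = 0.104), 3 (0.0765) or 4 (0.1) or paclitaxel replicate 1 (0.113), 3 (0.118) or 4 (0.0658). Its copy MTND6P4 (0.99 ± 0.30, uncertain) lost its call without combination replicate 2 (0.0806), 3 (0.0503) or 4 (0.0910) or paclitaxel replicate 1 (0.0824) or 3 (0.0960). The mitochondrial list had no call (3 of 13 rose and 1 fell, median 0.18), but passed in each set alone in opposite directions, with medians of −0.08 within replicates 1 and 2 (adjusted p = 0.00548) and 0.43 within replicates 3 and 4 (0.000145).

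Other lists that afatinib moved on top of paclitaxel were mostly lower. Replication genes fell in 24 of 28 cases and rose in 1 (CCNE2 −1.25 ± 0.10, UNG −0.93 ± 0.08), YAP/TEAD targets fell in 9 of 15 (F3 −1.26 ± 0.09), MAPK/ERK output fell in 10 of 18 and rose in 2 (SPRY4 −0.58 ± 0.07), immediate-early genes fell in 9 of 15 (JUNB −0.87 ± 0.10), mesenchymal genes in 5 of 12 and ribosomal proteins in 3 of 20. The EGFR family list fell in 6 of 12 and rose in 2, with the ligands HBEGF at −0.69 ± 0.07 and AREG at −0.82 ± 0.12, a list call lost without combination replicate 3 (adjusted p = 0.0555). The BCL2 list fell in 6 of 16 and rose in 1, lost without combination replicate 4 (0.0829) or paclitaxel replicate 3 (0.0552). Lysosome genes rose in 13 of 19 and fell in 1 (CTSD 0.47 ± 0.09), interferon-stimulated genes rose in 10 of 30 (IFIH1 0.71 ± 0.09) and genes of cholesterol synthesis and uptake in 9 of 24 (HSD17B7 0.48 ± 0.08). Heat shock genes rose in 4 of 11 (adjusted p = 0.0588) and passed with the replicate block (0.0377), without combination replicate 2 (0.0427) or 4 (0.0403), or without paclitaxel replicate 2 (0.0488) or 3 (0.0165). Adjusted over the list alone, 24 replication genes fell and 1 rose, 10 YAP/TEAD, 9 immediate-early and 5 mesenchymal genes fell, 14 MAPK/ERK genes fell and 2 rose, 6 EGFR family genes fell and 2 rose, 9 BCL2 family genes fell and 2 rose, 15 lysosome genes rose and 1 fell, and 10 interferon, 12 cholesterol and 4 heat shock genes rose, while the 3 ribosomal calls were lost. The list calls did not hold, with adjusted p = 0.0796 with an estimated correlation for MAPK/ERK, 0.101 for replication, 0.103 for YAP/TEAD, 0.140 for immediate-early, interferon and BCL2 genes, 0.230 for lysosome, 0.290 for mesenchymal genes, 0.353 for cholesterol and the EGFR family and 0.525 for ribosomal proteins. Of the 31 lists with a test 14 passed here and 3 also with an estimated correlation. In all 4347 genes changed (24.2% of those tested), 2268 higher and 2079 lower. The count was 1983 within replicates 1 and 2, 1299 within replicates 3 and 4, 768 without the concentration term and 80 (26 higher, 54 lower) with 1.5-fold as the null.

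The interaction asked where the combination departed from the sum of both single-drug log2 fold changes, which is the change in the paclitaxel response when afatinib is present. ASNS (ENSG00000070669, chromosome 7, 97852118 to 97872542), asparagine synthetase, stood at 83 ± 5.64 CPM in DMSO, 56.9 ± 2.73 with afatinib, 55.9 ± 9.79 with paclitaxel and 72.2 ± 12.1 in the combination, 0.91 ± 0.16 above the sum (adjusted p = 0.0183, 0.76 and 1.06 within the sets). The amino acid transporters SLC1A4 (0.90 ± 0.16) and SLC6A9 (0.73 ± 0.14) were above it too, as were the stress ligand gene ULBP2 (0.59 ± 0.13) and SNCAIP (0.52 ± 0.12). The histone genes HIST1H1C (−1.24 ± 0.19) and HIST1H2BK (−1.05 ± 0.13), CCNE2 (−0.91 ± 0.13), the lipid phosphatase gene PPAP2B (−0.86 ± 0.14) and FHDC1 (−0.83 ± 0.14) lay below the sum, HIST1H2BK standing at 20.7 ± 2.47 CPM with paclitaxel and 10.9 ± 1.35 in the combination. SLC6A9 lost its call without paclitaxel replicate 4 (adjusted p = 0.0553). ULBP2 lost it without afatinib replicate 2 (0.0638) or 4 (0.0561), DMSO replicate 4 (0.0628) or paclitaxel replicate 1 (0.0682) or 4 (0.0725). SNCAIP lost it without afatinib replicate 1 (0.0636), 2 (0.0664) or 3 (0.0986), combination replicate 2 (0.0960) or 3 (0.0769), DMSO replicate 4 (0.0826) or paclitaxel replicate 1 (0.1), 3 (0.0588) or 4 (0.108).

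Mitosis genes exceeded the sum of the single-drug changes. Of 30 tested, 11 were above it (median 0.35, 0.26 and 0.45 within the sets; adjusted p = 0.0140 with an estimated correlation), with KIF2C at 0.49 ± 0.07 and PLK1 at 0.41 ± 0.08. ATF4 targets were above it in 4 of 21 cases (median 0.28, 0.15 and 0.36 within the sets; 0.0362 with an estimated correlation), with CHAC1 at 1.02 ± 0.17. Replication genes lay below the sum in 5 of 28 cases (median −0.18, −0.21 and −0.18 within the sets; 0.289 with an estimated correlation), including UNG (−0.73 ± 0.12), E2F1 (−0.54 ± 0.09) and E2F2 (−0.71 ± 0.14). FOXO targets were below it in 3 of 16 (median −0.16, −0.27 and −0.13 within the sets; 0.164 with an estimated correlation). With p-values adjusted over the list alone, 28 mitosis genes and 9 ATF4 targets were above the sum and 10 replication genes and 6 FOXO targets below it, as were 4 immediate-early genes of 15, while 7 heat shock genes of 11 and 5 endoplasmic reticulum chaperones of 15 were above it. The list medians of the last 3 were −0.26 (−0.18 and −0.30 within the sets), 0.24 (0.20 and 0.28) and 0.24 (0.20 and 0.27), and their calls were lost with adjusted p = 0.289, 0.289 and 0.335 with an estimated correlation.

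A further 4 lists passed for the interaction at the preset correlation and depended on single libraries. MAPK/ERK output (median −0.12, −0.14 and −0.13 within the sets, SPRY2 −0.48 ± 0.08; adjusted p = 0.403 with an estimated correlation) lost its call without afatinib replicate 1 (0.0505), combination replicate 1 (0.0542) or 2 (0.0573), DMSO replicate 4 (0.0787) or paclitaxel replicate 2 (0.0691) or 3 (0.0659). Hypoxia genes (median −0.04, −0.18 and −0.02 within the sets, NDRG1 −0.49 ± 0.09; 0.556 with an estimated correlation) lost it without afatinib replicate 1 (0.0634), 2 (0.0861) or 3 (0.0745), combination replicate 1 (0.139) or 2 (0.0572), DMSO replicate 1 (0.0817) or 3 (0.0775), or paclitaxel replicate 2 (0.0691) or 3 (0.121). Lysosome genes (median 0.13, −0.04 and 0.26 within the sets; 0.608 with an estimated correlation) lost it with the replicate block (0.0521) and without afatinib replicate 4 (0.185), combination replicate 4 (0.419), DMSO replicate 2 (0.247) or 4 (0.104), or paclitaxel replicate 2 (0.0651) or 3 (0.0659). Mitochondrially encoded transcripts (median −0.28, −0.35 and −0.27 within the sets; 0.608 with an estimated correlation) lost it without afatinib replicate 3 (0.0745) or 4 (0.0542), combination replicate 1 (0.0613) or 2 (0.146), DMSO replicate 3 (0.158) or 4 (0.0559), or paclitaxel replicate 2 (0.141) or 4 (0.125). When adjusted over the list alone, 4 MAPK/ERK genes were below the sum and 1 above, and 1 hypoxia gene was below it.

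In all 159 genes departed from the sum, 70 above and 89 below it, and 26 of them by more than 2-fold (3 above, 23 below). The number depended on the fit: 501 with the replicate block, 3 within replicates 1 and 2, 4 within replicates 3 and 4, and with edgeR 0 without the concentration term, where 643 had an unadjusted p under 0.05. It was 367 with DESeq2 (200 above, 167 below), 479 without a filter on low counts (283 above, 196 below) and 189 without DMSO replicate 3 (125 above, 64 below). Leaving out 1 library gave 34 (paclitaxel replicate 4), 45 and 51 (combination replicates 3 and 2), 48, 62, 75 and 81 (afatinib replicates 3, 2, 1 and 4), 48 and 278 (paclitaxel replicates 1 and 2), and 64 and 103 (DMSO replicates 4 and 1).

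**Figure D4:**
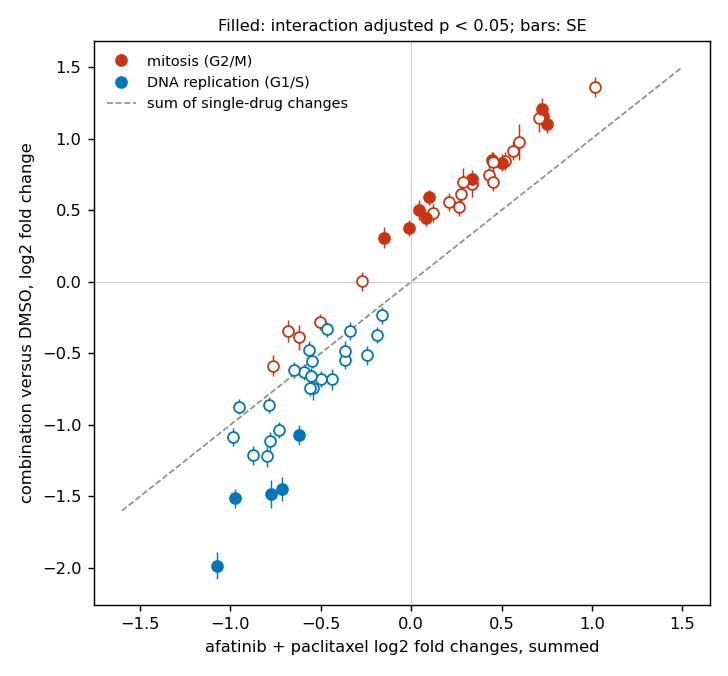
Log2 fold change in the combination against the sum of both single-drug log2 fold changes for members of the mitosis and DNA replication lists, with the line of equality; bars are SE and filled points have an interaction adjusted p under 0.05. The 11 filled mitosis genes lie above the line and the 5 filled replication genes below it.

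The responses to the single drugs overlapped with that to the combination more than with each other. Afatinib and the combination shared 2241 changed genes in the same direction and 74 in opposite directions (r = 0.622 across genes, which are not independent replicates), and paclitaxel and the combination shared 2526 and 72 (r = 0.652). Afatinib and paclitaxel shared 629 and 312 (r = 0.27). Independent lists of these sizes would share 300 higher and 353 lower, 288 and 416, and 140 and 215 genes, against the observed 1039 and 1202, 1007 and 1519, and 240 and 389. Because the DMSO libraries are common to each pair, 20 simulations of unchanged groups gave r = 0.502, 0.494 and 0.49. The covariances were 0.0882, 0.0973 and 0.0303 against simulated values of 0.0188, 0.0188 and 0.0187. With the DMSO libraries split between the comparisons they were 0.0698 and 0.0703, 0.0806 and 0.0794, and 0.0114 and 0.0131, and the genes shared in the same direction numbered 1276 and 1222, 1454 and 1633, and 301 and 260. Those in opposite directions were 75 and 67, 57 and 93, and 273 and 175. With the split r was 0.41 and 0.421, 0.454 and 0.449, and 0.081 and 0.095. For afatinib and paclitaxel, independent lists would then share 72 higher and 142 lower genes in one split and 53 and 99 in the other. The observed numbers were 89 and 212, and 94 and 166. No such number was computed for the 273 and 175 genes shared in opposite directions. These counts alone therefore do not show that the drugs tend to move genes in the same direction.

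Markers of cell types other than breast cancer epithelium were measured to see what else the cultures expressed. Of 3 tested blood cell markers, LAPTM5 stood at 349 ± 120 CPM in DMSO and 402 ± 172 in the combination (0.17 ± 0.08). It passed with the replicate block (adjusted p = 0.0438) and, among the leave-outs, only without DMSO replicate 4 (0.0334). ITGAM rose in the combination from 0.14 ± 0.11 to 0.67 ± 0.12 CPM (2.29 ± 0.37) and CD14 with paclitaxel from 0.57 ± 0.15 to 1.21 ± 0.47 CPM (1.07 ± 0.19). Of 5 endothelial markers, CDH5 fell with afatinib (−1.69 ± 0.25) and in the combination (−2.44 ± 0.27) from 1.5 ± 0.89 CPM in DMSO. Of 2 tested fibroblast markers, PDGFRB fell in the combination (−0.75 ± 0.13) and COL1A1 differed by 0.16 ± 0.09. Among the leave-outs COL1A1 passed only without combination replicate 1 (adjusted p = 0.0349). Of 6 luminal breast markers, GATA3 fell in the combination (−0.48 ± 0.08). None of the 3 lists large enough for a test passed with afatinib (camera adjusted p = 0.264 for blood, 0.251 for endothelial and 0.856 for luminal markers). Blood markers did not pass with paclitaxel (median 1.07, 0.90 and 0.94 within the sets, adjusted p = 0.0635), and passed there without DMSO replicate 4 (0.0300) or paclitaxel replicate 1 (0.0261). In the combination (adjusted p = 0.0932) they passed without DMSO replicate 4 (0.0493). Endothelial markers in the combination versus paclitaxel (adjusted p = 0.0526) passed without combination replicate 1 (0.0177), paclitaxel replicate 1 (0.0278) or paclitaxel replicate 3 (0.0305). Epithelial genes had no list call in the combination, where 3 of 11 fell and 1 rose (median 0.12, −0.00 and −0.18 within the sets). MHC class I genes, several of which were split over alternative assemblies and are uncertain, had medians of 0.03 with afatinib (0.06 and 0.00 within the sets), −0.11 with paclitaxel (−0.09 and −0.08) and 0.06 in the combination (−0.04 and 0.20) with no list call. Counts adjusted over the list alone were 1 blood marker higher with afatinib, 2 with paclitaxel and 2 in the combination, 1 endothelial marker lower in the combination versus paclitaxel, 1 endothelial marker lower and 3 epithelial genes lower and 1 higher in the combination.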

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

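All tests of the mitochondrial share and of the histone genes, and those of scaling and of the share of mitotic cells below, were chosen only after the result was seen, while the splits of the samples and the leave-outs were planned. What marked 4 results was a difference between groups, namely between the paclitaxel response with and without afatinib by the interaction term: 159 genes, the mitosis list (median 0.349), ATF4 targets (0.278) and DNA replication genes (−0.182). Single libraries were compared with their group in 56 groups of 4 values by Dixon's 95% rule, and none passed. Each group held 2 libraries of each concentration set, so the rule could hardly mark a library where the sets differed. The 2.8 marks that chance would give assume values without that split. The absence of marks therefore does not show that no library stood apart.

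Other splits of the samples were refitted. In each of the 5 comparisons between groups, the real labels were the only 1 of 35 splits with as many calls, the highest other counts being 1 for afatinib, 4 for paclitaxel, 702 for the combination, 0 versus afatinib and 2 versus paclitaxel. Of these splits 8 part all 4 pairs of the same replicate number. Among those the highest other count was 1 for afatinib and 0 for the rest, the 702 coming from a split that parts fewer pairs, and 1 of 8 is the smallest share they allow. For the interaction 6 of 100 relabellings within the sets, the real one included, reached 159, and the highest other called 863, so chance is not excluded for this count. The relabelled contrasts of the 5 others resembled a drug contrast, meaning libraries with against without 1 of the drugs. Their absolute correlation with it over the 16 libraries was 0.5 to 0.75. In 74 relabellings this correlation was at most 0.25, a limit set after the result was seen, and these called at most 2.

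Mitosis genes lay above the sum of the single-drug changes. Scaling of the libraries is argued against, since replication genes went the other way and the lists differed by 0.531. So is 1 library alone, because the median stayed at 0.322 to 0.422 over the leave-outs. A larger share of cells in mitosis when both drugs are given cannot be told apart from regulation of these genes within cells. The 55 mitotic genes outside the list had a median of 0.351, with CDC25B at 0.47 ± 0.08, CDCA8 at 0.46 ± 0.08 and TACC3 at 0.44 ± 0.08, and they do not decide it because they were chosen after the pattern was seen.

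The mitochondrial share of counts was higher in treated than in DMSO libraries. A lower RNA concentration cannot be told apart from the treatment: in 5 of 8 pairs of libraries of the same group and set the lower concentration went with the higher share (two-sided exact p = 0.727), too few to decide. A change of all mitochondrially encoded mRNAs by 1 factor is argued against, since 6 of 13 had an interval that excluded the list median with afatinib (log2 fold changes −0.32 to 1.52).

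Clustered histone genes were higher with paclitaxel, 10 of 29 rising and 4 falling. A larger share of cells in S phase cannot be decided from the replication list, which fell (median −0.488). That list measures transcript levels rather than the share of cells in S phase, and its fall was known when the test was chosen. Capture of more transcripts without a poly(A) tail cannot be told apart: 0 histone genes with an average log2 CPM of at least 0 fell, and the 4 that fell were below that level. A change in histone transcription or processing was not tested.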

How the results depend on the processing

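The settings with a linear RNA concentration or with both libraries of the highest mitochondrial share left out hold tests chosen only after the result was seen. Counts below are in the order afatinib, paclitaxel and combination versus DMSO, combination versus afatinib, combination versus paclitaxel, and interaction, against 3432, 3694, 6830, 4935, 4347 and 159 as reported. Without the concentration term they were 380, 625, 2310, 1143, 768 and 0 (edgeR; 643 interaction genes at an unadjusted p under 0.05). Within replicates 1 and 2 they were 1243, 1798, 4671, 2533, 1983 and 3, and within replicates 3 and 4 they were 516, 772, 3169, 2003, 1299 and 4, where each set holds 2 libraries per group. With 1.5-fold as the null they were 57, 66, 471, 107, 80 and 0 (208 interaction genes unadjusted), a null that removes small changes by construction. On the authors' corrected table with limma they were 1108, 1148, 4067, 2113, 2170 and 2; its correction was fitted without the treatment, which differs in concentration, so part of the treatment difference is removed by construction. With the linear concentration afatinib versus DMSO had 1374, the combination versus paclitaxel 2415 and the interaction 14. Only the interaction moved by more than 1.5 times with the log2 concentration (26, while the others were 2294, 5407, 7009, 4654 and 3028), DESeq2 (367), no filter on low counts (479) and both high mitochondrial libraries left out (58). The called genes changed more than these totals: with the log2 concentration 2014, 2565, 4688, 3808 and 3013 of the genes reported for the 5 comparisons between groups were called again in the same direction, and with the linear concentration 1363, 2296, 4398, 3344 and 2402. The cause was not tested except where the setting's construction gives it.

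The replicate block, which pairs libraries by number, gave 501 interaction genes and 4446, 4609, 7681, 5853 and 5373 for the other comparisons. It ended the interaction call of the lysosome list and added list calls for FOXO and YAP/TEAD targets with paclitaxel, immediate-early genes in the combination versus afatinib and heat shock genes in the combination versus paclitaxel, and a call for LAPTM5 in the combination. It changed no other call of a named gene or list, and the cause was not tested.

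Leaving out 1 library gave 2514 to 3221 genes for afatinib, 2965 to 3556 for paclitaxel, 5974 to 6531 for the combination, 4040 to 4621 for the combination versus afatinib, 3340 to 4293 for the combination versus paclitaxel and 34 to 278 for the interaction. Of 1784 values of named genes under these leave-outs 1747 kept their side of the threshold and direction, 34 lost and 3 gained a call, and of 1736 list values 1621 kept it, 57 lost and 58 gained. Calls shared in the same direction were 39, 292 and 452 without the concentration term for afatinib with paclitaxel, afatinib with the combination and paclitaxel with the combination, and 301 and 260, 1276 and 1222, and 1454 and 1633 with the DMSO libraries split, against 629, 2241 and 2526. The split leaves fewer samples per comparison.

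All values of named genes kept their side of the threshold with DESeq2, limma-voom, RLE factors and library sizes without abundant genes, 200 without a filter, 130 without the concentration term (72 lost), 92 with 1.5-fold as the null (110 lost), 161 on the authors' table (41 lost), 182 with the log2 concentration (15 lost, 5 gained), 171 with the linear concentration (29 lost, 2 gained), 196 with both high mitochondrial libraries left out (5 lost, 1 gained), 164 within replicates 1 and 2 and 170 within replicates 3 and 4. These shares flatter the fits, since list members were picked for the text with the call's stability known: CITED2 and KIF11, whose interaction calls were lost on leaving out single libraries, were left out of the text after this was seen. Of 74 list calls among 186 list tests 14 held with an estimated correlation and 60 were lost, and with fry 12 were lost and 30 gained. List calls lost and gained were 18 and 7 without the concentration term, 5 and 12 within replicates 1 and 2, and 13 and 10 within replicates 3 and 4. The median of mitochondrially encoded transcripts reversed in the combination versus paclitaxel within replicates 1 and 2 (−0.08), and the cause was not tested.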

Other observations

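All tests in this part were chosen only after the result was seen, on 4 lists made with the changes of some members already known. Their values are therefore given without a p and describe these genes only. Genes of the actin cytoskeleton and of SRF, the transcription factor that responds to actin assembly, fell with afatinib in 17 of 24 cases (median −0.34), among them FBLIM1 (−0.70 ± 0.06), ACTG1 (−0.66 ± 0.07), the actin-binding protein gene DBN1 (−0.74 ± 0.07) and TAGLN (−0.75 ± 0.08). They fell in 17 of 24 in the combination (median −0.29) and in 15 of 24 in the combination versus paclitaxel (median −0.27). With paclitaxel 2 rose and 5 fell (median −0.01), in the combination versus afatinib 6 rose and 1 fell (median 0.15), and the interaction median was 0.13. Cytosolic aminoacyl-tRNA synthetase genes, which load amino acids on tRNA, fell with afatinib in 10 of 19 cases (median −0.20), including GARS (−0.42 ± 0.06), WARS (−0.42 ± 0.06), CARS (−0.45 ± 0.07) and SARS (−0.36 ± 0.06). With paclitaxel 7 of 19 fell (median −0.12) and in the combination 10 of 19 (median −0.14). In the combination versus afatinib 5 rose (median 0.09), and versus paclitaxel 1 rose and 2 fell (median −0.02). For the interaction 4 of 19 lay above the sum (median 0.22), with WARS and MARS at 0.41 ± 0.09 each.

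Clustered histone genes with paclitaxel had a median of 0.31, with HIST2H2BE at 2.40 ± 0.19, HIST1H2AC at 2.18 ± 0.16 and HIST1H4I at 1.71 ± 0.12, while HIST1H4B fell by 2.22 ± 0.46. In the combination 8 of 29 rose and 2 fell (median 0.02). For the interaction the histone median was −0.36 and 5 lay below the sum. Mitotic genes outside the fixed list rose in 42 of 55 cases and fell in 6 in the combination (median 0.55). With paclitaxel alone 28 rose and 13 fell (median 0.19), and with afatinib alone 5 rose (median 0.03).

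Set-specific log2 fold changes from replicates 1 and 2 and from replicates 3 and 4 correlated over 9718 genes by 0.84 for afatinib, 0.80 for paclitaxel, 0.86 for the combination and 0.50 for the interaction.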
